A study of Mus musculus with 6 samples.

How the data were processed

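Gene expression was measured in sorted bone marrow cells of adult mice with Affymetrix 3' expression arrays, 1 sample per array. Per the labels' protocols, cells were sorted directly into lysis buffer, RNA was prepared with a column kit for small samples, and biotin-labelled cRNA was made in a small-sample protocol with 2 rounds of amplification. Amplification of this kind favours the 3' end of transcripts, so a change in transcript end can read as a change in level. The samples were grouped by their titles into WT LMPP, E2A-KO LMPP and WT LSK FLT3-, each with 2 arrays; another free-text label calls all samples wild-type LMPP and was set aside because the titles and source names differ between samples.

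The deposited values are probe set intensity values on a linear scale, made with RMA per the submitters' processing notes, which give no version. RMA corrects the background, normalizes arrays to a common distribution and summarises the probes of a probe set on the log2 scale. The deposited values run from 4.23 to 25594, so log2 was taken before any test. Whether all arrays were normalized in 1 run is not given in the sources used here, and the quartiles of the LSK FLT3- arrays differ from those of the LMPP arrays. No detection calls were used, and values near or below the array median of about 4 (log2) lie in the compressed low range of the arrays, where fold changes are understated. For arrays there is no read depth; the number of arrays limits the precision.

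Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. By Entrez ID 34754 probe sets matched a reference gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. The build behind the annotation is not given, so no coordinates are printed, and the table served for names and gene order. Each of 18194 genes was represented by the probe set with 1 symbol and the highest mean over the 6 arrays. Probe sets with several symbols or none were tested only as probe sets and name no gene.

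Tests were made with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group on all 6 arrays, which left 3 residual degrees of freedom, and moderated variances with 5.8 prior degrees of freedom. All 6 arrays entered each fit so that the 3 comparisons shared 1 estimate of the spread. P-values were two-sided and adjusted by Benjamini and Hochberg, with a threshold of 0.05. SDs are between the 2 arrays of a group, and SEs are from the model. The gene lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. Of 18 gene lists, 16 were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives; the gate markers and the sex-linked genes were only described. A list is counted over its measured members.

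The genes named follow a rule: the E protein and Id network, the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap between the groups (5 and 5 for E2A-KO LMPP against WT LSK FLT3-), and up to 4 members of each list with the largest change past the threshold, or up to 2 where none passed. Genes named for another reason are said to have been chosen after their values were seen. The covariance that the shared WT LMPP arrays add between the stage and knockout changes was estimated from 100 simulations with no effect. These do not correct the number of genes called in both, which was counted again with 1 WT LMPP array given to each comparison, an alternative added after the data were seen.

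The alternatives were a block for the replicate number, a fit on only the 4 arrays of a comparison, leaving out the dimmest 40% of genes, the mean of all probe sets of a gene, quantile normalization of the 6 arrays, centring on array medians, a variance trend with robust estimation, leaving out each array in turn, all probe sets as the unit, a 2-fold minimum and an adjusted p under 0.1. The replicate numbers are not said to pair samples across groups. A fit with 1 array left out leaves 1 array in a group, which is assumed to vary like the other groups. Where that group is outside the comparison, the fit is the same as that on only the 4 arrays of the comparison. The alternatives then count that fit more than once.

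The test was checked on simulated data made for E2A-KO LMPP against WT LMPP over 18194 genes, with 200 changed genes in each of 20 simulations. It recovered 18.2% of genes changed by 0.5 (log2), 97.3% of those changed by 1 and 100% of those changed by 2, and 6.94% of calls were false. A shift of the lymphoid priming list by 0.5 was recovered in 20 of 20 simulations, with 0 false calls among 280 tests of lists without a shift. The simulated genes varied independently, with the same spread in each group. The check therefore does not cover lists whose members vary together or groups that differ in spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.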

Results

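RNA was measured on 6 Affymetrix arrays from sorted mouse bone marrow cells, in 3 groups of 2 arrays. WT LMPP and E2A-KO LMPP were lineage-negative, SCA1-positive, KIT-positive cells with high FLT3 on the surface, a fraction known as lymphoid-primed multipotent progenitors. WT LSK FLT3- were cells of the same lineage, SCA1 and KIT gate without surface FLT3, the fraction that holds hematopoietic stem cells. E2A proteins are basic helix-loop-helix transcription factors encoded by Tcf3, and the knockout mice were on a C57BL/6 background. The series design text names both genotypes for LSK FLT3- as well as LMPP, but none of the 6 samples is titled as knockout LSK FLT3-, so the effect of the genotype was measured in LMPP alone. Nothing in the labels says whether the arrays of a group came from separate mice or sorts, so the p-values measure only the spread between these arrays, which may be technical.

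Each array gave 45101 probe set values, with a median of 4.01 to 4.04 (log2) on the LMPP arrays and 3.90 and 3.91 on the LSK FLT3- arrays. Replicates correlated across probe sets with Pearson's r = 0.989 in WT LMPP, 0.990 in E2A-KO LMPP and 0.996 in WT LSK FLT3-, against 0.985 between the LMPP genotypes and 0.966 to 0.972 between LMPP and LSK FLT3- arrays. Probe sets are not independent replicates. The first principal component held 70.1% of the variance and parted the LSK FLT3- arrays from the 4 LMPP arrays, and the second held 13.5% and parted the LMPP genotypes. The value distribution differed by cell fraction: the upper quartile was 6.13 and 6.15 (log2) on the LSK FLT3- arrays and 5.78 to 5.82 on the LMPP arrays. The difference between 3' and 5' Actb control probe sets, a sign of RNA length, was 3.45 and 3.55 (log2) on the LSK FLT3- arrays and 3.77 to 3.95 on the LMPP arrays. The same difference for Gapdh was 3.25 and 3.44 on the LSK FLT3- arrays and 3.09 to 3.35 on the LMPP arrays, so it overlapped and did not go the same way. Xist lay between 10.9 and 11.3 (log2) on all 6 arrays, and Eif2s3y, which is on the Y chromosome, between 6.50 and 7.37. Of the other Y chromosome genes measured, Kdm5d lay between 5.45 and 6.39. Uty was at 3.58 to 3.68 on the LMPP arrays, below the array median, and at 4.43 and 4.89 on the LSK FLT3- arrays.

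The stated goal of the experiment was to find expression changes between wild-type and knockout LMPP. Tcf3, the targeted gene, had 3 probe sets, with levels of 6.90 ± 0.05, 4.20 ± 0.25 and 3.49 ± 0.29 (log2, SD, n = 2) in WT LMPP and 6.66 ± 0.19, 4.11 ± 0.24 and 3.16 ± 0.04 in E2A-KO LMPP, and none changed. Where these probe sets lie relative to the targeted part is not given in the sources used here, so Tcf3 does not check the labels.

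Lymphoid genes and neutrophil granule genes held the largest falls in E2A-KO LMPP. Il7r, a chain of the interleukin-7 receptor, averaged 8.47 ± 0.33 (log2, SD, n = 2) in WT LMPP and 4.66 ± 0.11 in E2A-KO LMPP, a change of -3.81 (SE 0.17, adjusted p = 2.77e-05), or 14-fold. Ccr9, a chemokine receptor of thymus-homing progenitors, fell by 3.22 (SE 0.19, adjusted p = 0.000115), and Ngp, a neutrophil granule protein, fell by 3.59 (SE 0.14, adjusted p = 1.74e-05). Lypd6b rose from 3.26 ± 0.23, below the array median, to 6.91 ± 0.05, a measured change of 3.65 (SE 0.15, adjusted p = 1.74e-05).

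Of 18194 genes tested, 250 changed between E2A-KO and WT LMPP: 69 rose and 181 fell. At least a 2-fold change was seen in 123 of them, 29 higher and 94 lower. After Il7r, Ngp and Ccr9, the largest falls were Ltf, which encodes the granule protein lactoferrin (-3.48), Arpp21 (-3.02), Lcn2, a neutrophil granule lipocalin (-2.83), Hmga2, a chromatin protein of fetal and stem cells (-2.78), Gimap8, a GTPase of the immune-associated family (-2.56), Cnn3 (-2.39) and Cmah, a sialic acid hydroxylase (-2.26). Beside Lypd6b, the largest measured rises were Chl1, a neural cell adhesion molecule (3.44, SE 0.35), the receptor phosphatase Ptprf (2.22), the short-chain fatty acid receptor Ffar2 (2.03), Auts2 (1.94), the C-type lectins Clec4d (1.94) and Clec4e (1.85), S100a4 (1.85), the mucin Muc13 (1.78) and the cytokine receptor Il31ra (1.78). Each of these 20 genes kept its call under all 13 alternative settings run on single genes. Among these settings, the fits without an LSK FLT3- array are the same as that on the 4 LMPP arrays alone. Chl1 varied most between arrays, with log2 values of 4.28 and 3.23 in WT LMPP and 6.81 and 7.59 in E2A-KO LMPP. Lypd6b and Chl1 in WT LMPP, and Ccr9, Ltf and Lcn2 in E2A-KO LMPP (3.74, 3.90 and 3.40), lay below the array median, so the exact size and rank of their changes carry no weight.

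The lymphoid priming list had 19 measured members, of which 9 fell in E2A-KO LMPP, 0 rose and 10 did not pass. Besides Il7r, Ccr9 and Cnn3, these included the recombinase gene Rag1, which fell by 2.12 (SE 0.23, adjusted p = 0.00351). The remaining 5 were Blnk (-1.84), Ets1 (-1.63), Dntt (-1.59), Notch1 (-1.29) and Rag2 (-1.18). They are named to complete the list, a choice made after their values were seen. Dntt, the terminal transferase gene, was still at 11.28 (log2) in E2A-KO LMPP, against 12.87 in WT LMPP. The list's median change was -0.67, and 13 members fell when p was adjusted over the list alone. The list as a whole stood lower than other genes (limma camera, adjusted p = 5.97e-19), and the call was lost at adjusted p = 0.0575 with an estimated correlation, the highest of 15 alternatives (lowest 3.73e-19).

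**Figure D1:**
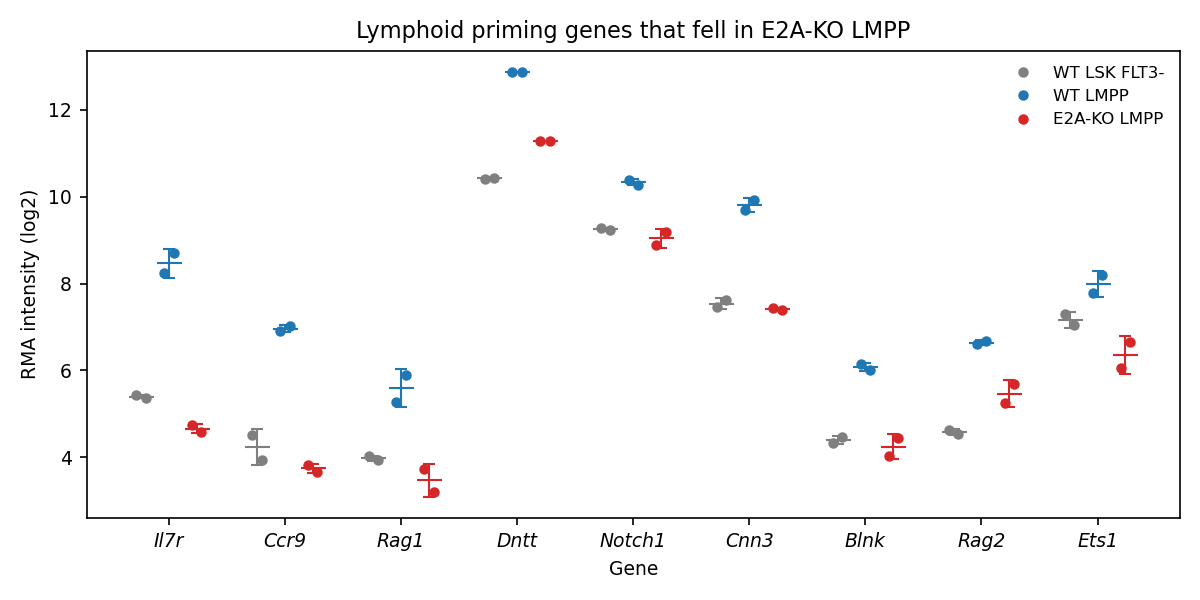
RMA intensity (log2) of the 9 lymphoid priming genes that fell in E2A-KO LMPP, with points for single arrays and bars for the group mean and SD (n = 2 arrays per group). Il7r averaged 8.47 in WT LMPP, 4.66 in E2A-KO LMPP and 5.40 in WT LSK FLT3-, while Dntt averaged 12.87, 11.28 and 10.42.

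The mature myeloid list, chosen as markers of another cell type that the gate could hold, had 12 measured members. In E2A-KO LMPP 7 of them fell and 0 rose, with a median change of -1.36. Besides Ngp, Ltf and Lcn2, the chitinase-like gene Chil3 fell by 1.98 (SE 0.19, adjusted p = 0.00176). The other 3, completing the list after their values were seen, were S100a8 (-1.72), Camp (-1.37) and S100a9 (-1.36). Lysozyme, Lyz2, chosen after its values were seen, was at 8.24 in WT LMPP and 7.76 in E2A-KO LMPP and did not pass (adjusted p = 0.154). Adjusted over the list alone, 9 members fell. The list stood lower in E2A-KO LMPP (camera, adjusted p = 4.64e-14; adjusted p = 0.0575 with an estimated correlation, the highest of 15 alternatives, lowest 2.22e-15).

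Interferon response genes also fell in the knockout, 7 of 13 measured, with 0 rises and a median change of -0.88. Ifit1 fell by 1.00 (SE 0.12, adjusted p = 0.0062), and Ifi27l2a, Ifit2 and Ifit3 fell by 1.00, 0.97 and 0.90. All 13 members had a change below 0, and 11 fell when adjusted over the list alone. The list stood lower (camera, adjusted p = 4.46e-14; adjusted p = 0.0575 with an estimated correlation, the highest of 15 alternatives, lowest 2.22e-15). Leaving out 1 array ended single calls: for Ifit3 any of the 6 arrays did (adjusted p 0.0558 to 0.118), for Ifit2 either E2A-KO LMPP array (0.0606 and 0.0672), and for Ifi27l2a E2A-KO LMPP replicate 2 or either LSK FLT3- array (0.052 to 0.0672).

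B lineage genes had 16 measured members, of which the surrogate light chain gene Vpreb1 fell by 1.76 (SE 0.21, adjusted p = 0.00541) and the other 15 did not pass. Ebf1 and Cd79a, chosen after their values were seen, were at 3.75 and 4.11 (log2) in WT LMPP and at 3.41 and 3.54 in E2A-KO LMPP, in the low range of the arrays, and did not pass. The list stood lower (camera, adjusted p = 0.0346; adjusted p = 0.393 with an estimated correlation; range 0.00986 to 0.436 over 15 alternatives), with 2 members lower when adjusted over the list alone. The immediate early and stress list also stood lower (camera, adjusted p = 0.0458; adjusted p = 0.305 with an estimated correlation; range 0.0115 to 0.305), through falls of Klf4 (-1.13) and the heat shock gene Hspa1b (-0.87) among 19 members, or 6 members adjusted over the list alone. Leaving out WT LMPP replicate 1 or E2A-KO LMPP replicate 1 ended the calls of both lists (adjusted p 0.135 and 0.295 in each), and leaving out WT LMPP replicate 2 ended that of the immediate early list (0.0526), as did the mean of all probe sets (0.0842) and median centring of the arrays (0.056). The B lineage call was also lost without the dimmest 40% of genes (0.436) and with fry (0.0736), and the immediate early call with fry (0.0559). Vpreb1 lost its call without E2A-KO LMPP replicate 1 (0.0581), Hspa1b without any 1 of the 6 arrays (0.0558 to 0.161), and Klf4 without any but E2A-KO LMPP replicate 2 (0.0758 to 0.126) and with the mean of all probe sets.

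In the E protein and Id network, Id2, an inhibitor of E proteins, fell by 1.38 (SE 0.21, adjusted p = 0.0181), and the other 8 members did not pass. Adjusted over the list alone, 1 member fell, and the list did not stand apart (camera, adjusted p = 0.199), except without the dimmest 40% of genes (0.0335). Tcf4, at -0.46, passed only with a trend in the variance (adjusted p = 0.0309). Removing any 1 array other than E2A-KO LMPP replicate 2 ended the Id2 call (adjusted p 0.0553 to 0.0758). In single list members outside these groups, the granulocyte and monocyte receptor gene Csf1r fell by 1.13 (adjusted p = 0.00811; 0.0668 without E2A-KO LMPP replicate 1), and Prtn3 (0.65), Nkg7 (0.83) and Thy1 (1.02) rose. The last 3 calls were lost without any 1 of the 6 arrays (adjusted p 0.106 to 0.156, 0.0535 to 0.129, and 0.0643 to 0.164), that of Prtn3 also with a median centring or quantile normalization of the arrays. With the replicate number as a block the calls of Thy1 (0.0628) and Prtn3 (0.0797) were lost too.

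Stem cell genes did not pass in either direction: 0 of 20 changed, with a median of 0.02 and the largest differences in Fgd5 (-0.77) and Ndn (-0.74). Neither did any of the 19 megakaryocyte and erythroid, 27 cell cycle, 10 cell cycle inhibitor, 14 ribosomal protein and 12 bone marrow stroma genes measured. Over these 6 lists, adjusted over the list alone, only 3 stem cell genes fell. Adjusted over the list alone, 3 rose and 4 fell among 15 granulocyte and monocyte progenitor genes, 2 rose and 1 fell among 15 T lineage genes, 1 rose among 15 NK and dendritic cell genes, and 1 fell among 14 Notch pathway genes, which is the Notch1 counted above. None of these lists stood apart (camera, adjusted p 0.133 to 0.878). Fgd5 passed only without WT LMPP replicate 1 (adjusted p = 0.0325) and Ndn only with a trend in the variance (0.0226). Car1, an erythroid gene at 0.74, passed only without WT LMPP replicate 2 (1.22, adjusted p = 0.0133). The gate markers Flt3 and Kit describe the sort and did not pass either, at -0.07 and -0.32.

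The test was limma's moderated test on all 6 arrays with Benjamini-Hochberg adjustment, and the 2 LSK FLT3- arrays entered the estimate of the spread and were closer to each other (SD of the log2 difference 0.195) than the WT LMPP (0.308) or E2A-KO LMPP (0.287) arrays. On the 4 LMPP arrays alone 89 genes passed, 19 higher and 70 lower, all 89 among the 250, and leaving out 1 array gave 151 and 164 (WT LMPP replicates 1 and 2), 93 and 107 (E2A-KO LMPP) and 89 and 89 (LSK FLT3-).

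**Figure D2:**
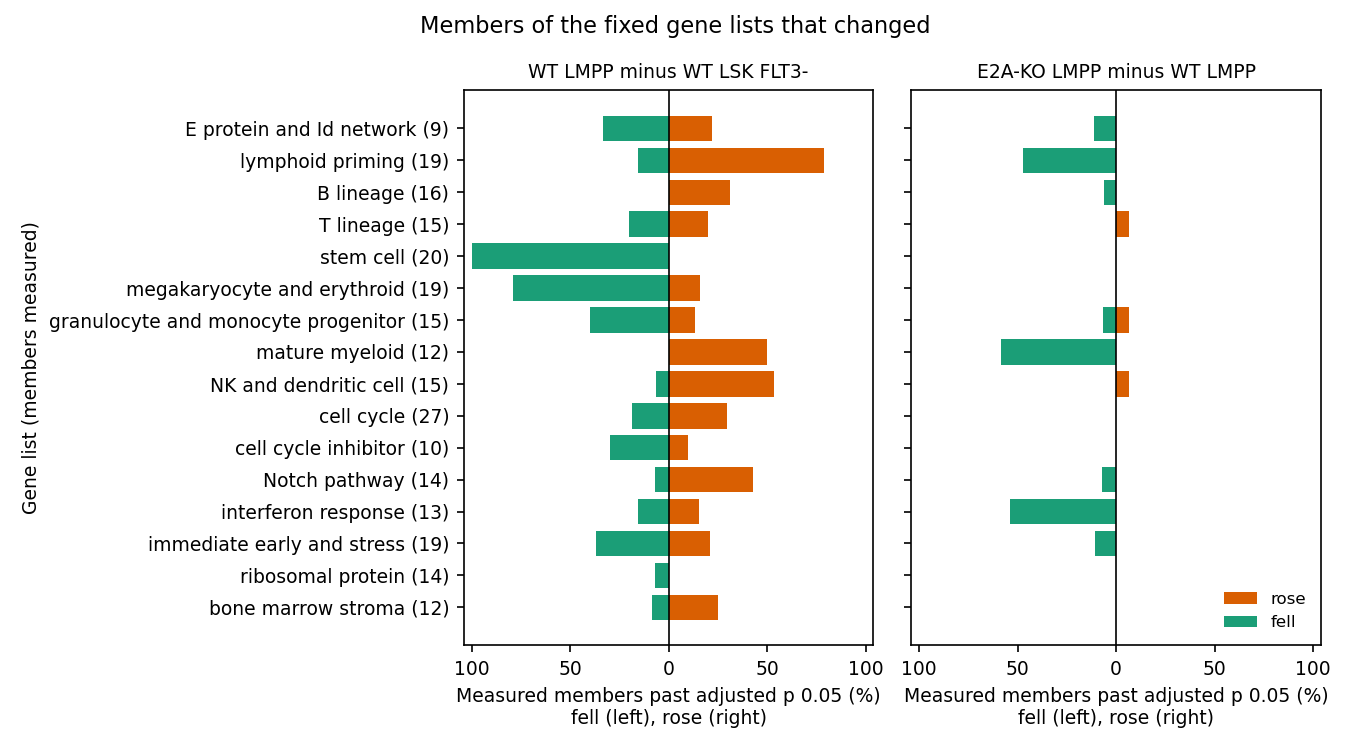
Percent of measured members of each fixed list that passed the threshold, fallen to the left and risen to the right, for WT LMPP minus WT LSK FLT3- and E2A-KO LMPP minus WT LMPP (n = 2 arrays per group, members measured in brackets). All 20 stem cell genes fell from LSK FLT3- to LMPP and 0 changed with the genotype, whereas 9 of 19 lymphoid priming and 7 of 12 mature myeloid genes fell in E2A-KO LMPP.

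The comparison of the wild-type fractions gives the change between the FLT3-negative and FLT3-high stages. From WT LSK FLT3- to WT LMPP 15 of 19 lymphoid priming genes rose, and 20 of 20 stem cell genes and 15 of 19 megakaryocyte and erythroid genes fell. As lists none of these kept its call with an estimated correlation (adjusted p = 0.124, 0.0694 and 0.0939). Il7r was 3.07 higher (log2, SE 0.17, adjusted p = 1.33e-05), and the class II chaperone gene Cd74 was 2.99 higher (SE 0.14, adjusted p = 5.92e-06). Tek, the angiopoietin receptor of stem cells, fell from 6.11 to 3.09 (change -3.01, SE 0.15, adjusted p = 6.68e-06), and Car1, an erythroid carbonic anhydrase, fell by 4.08 (SE 0.26, adjusted p = 2.71e-05). Igha, an immunoglobulin heavy chain gene, had the largest fall among genes with a single-symbol probe set, from 10.05 ± 0.11 in WT LSK FLT3- to 4.26 ± 0.34 in WT LMPP (-5.79, SE 0.18, adjusted p = 1.08e-06).

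Between these fractions 6198 genes changed, 1889 higher and 4309 lower in WT LMPP (30.5% higher), and 1214 changed at least 2-fold, 237 higher and 977 lower. The 10 largest rises were Plbd1 (3.39), Wfdc17 (3.31), the macrophage perforin gene Mpeg1 (3.13), Il7r, Cd74, H2-Eb1 (2.85), Ccr9 (2.73), H2-Ab1 (2.70), H2-Aa (2.69) and Slc35d3 (2.64). After Igha, the largest falls were the transglutaminase gene Tgm2 (-5.50), the vesicular monoamine transporter gene Slc18a2 (-5.01), Grb10 (-4.89), the immunoglobulin joining chain gene Jchain (-4.77), Car1, Aldh1a1 (-4.07), Dach1 (-3.84), the mast cell protease gene Cpa3 (-3.74) and Apoe (-3.58). For Grb10, 1 of 3 probe sets changed in the opposite direction and passed. All 20 kept their calls under the 13 alternatives, where the fits without an E2A-KO LMPP array are the same as that on the 4 wild-type arrays alone. In WT LMPP Slc18a2 (2.57), Jchain (3.17), Grb10 (3.93), Car1 (3.81), Aldh1a1 (3.17), Dach1 (3.14) and Cpa3 (3.57) lay below the array median, so the exact size and rank of these falls carry no weight.

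All 20 measured stem cell genes fell from LSK FLT3- to LMPP, with a median of -1.86. Besides Tek, Vwf fell by 2.86, Gata2 by 2.83 and Pdzk1ip1 by 2.70. The list stood lower (camera, adjusted p = 5.36e-15; adjusted p = 0.0694 with an estimated correlation, the highest of 15 alternatives, lowest 2.02e-19). Of 19 megakaryocyte and erythroid genes, 15 fell and 3 rose, with Aqp1 (-3.02), the integrin gene Itga2b (-2.82) and Pf4 (-2.47) after Car1. The 3 rises were Hba-a1, Alas2 and Tfrc (0.73, 0.72 and 0.52), named after their values were seen. This list stood lower (camera, adjusted p = 2.06e-06; adjusted p = 0.0939 with an estimated correlation, the highest of 15 alternatives, lowest 4.99e-09). Adjusted over the list alone, the counts of both lists were the same.

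Of 19 lymphoid priming genes, 15 rose and 3 fell, with the same counts adjusted over the list alone and a median of 1.08. Dntt rose by 2.45 (SE 0.12) beside Il7r and Ccr9. Jchain fell, as did Foxo1 (-0.79) and Ltb (-0.44), the last 2 named after their values were seen. The list stood higher (camera, adjusted p = 1.67e-07; adjusted p = 0.124 with an estimated correlation, the highest of 15 alternatives, lowest 4.50e-10). NK and dendritic cell genes rose in 8 cases and fell in 1 of 15, the same adjusted over the list alone, and the highest were the antigen presentation genes Cd74, H2-Eb1, H2-Ab1 and H2-Aa (camera, adjusted p = 0.000463; adjusted p = 0.156 with an estimated correlation, the highest of 15 alternatives, lowest 1.82e-06). Of 12 mature myeloid genes 6 rose, or 7 adjusted over the list alone, among them Camp (1.52), Ltf (1.34) and Ngp (0.97), so these neutrophil genes were higher in WT LMPP than in both other groups (camera, adjusted p = 0.00231; adjusted p = 0.239 with an estimated correlation, the highest of 15 alternatives, lowest 1.26e-05).

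B lineage genes rose in 5 of 16 cases, the same adjusted over the list alone, with Ebf1 and Igll1 both 0.81 higher (camera, adjusted p = 0.0191; adjusted p = 0.322 with an estimated correlation; range 0.0144 to 0.361). Quantile normalization ended this call (camera, adjusted p = 0.0659). Leaving out the dimmest 40% of genes did too (0.361), with a list median of -0.132. The mean of all probe sets ended the call of Igll1 (limma, adjusted p = 0.178). Ebf1 (3.7 in WT LMPP, 2.9 in WT LSK FLT3-) and Cd79a (4.1 and 3.4) lay in the low range of the arrays. Notch pathway genes rose in 6 of 14 cases and fell in 1, the same adjusted over the list alone, with Notch1 1.08 and Notch2 0.90 higher (camera, adjusted p = 0.0198; adjusted p = 0.239 with an estimated correlation; range 0.000174 to 0.239). This call was lost without LSK FLT3- replicate 2 (adjusted p = 0.0539), with quantile normalization (0.0634) and with the mean of all probe sets (0.0966). In the E protein and Id network, Id2 (1.58) and Tcf4 (1.16) rose, and Tal1 (-1.19), Tcf12 (-0.84) and Tcf3 (-0.44) fell. The Tcf3 call (limma, adjusted p = 0.0417) was lost with quantile normalization (0.863) and without any 1 of the WT LMPP or LSK FLT3- arrays. In the limma fit on all probe sets, the probe set behind this call did not pass (adjusted p = 0.0608). Another Tcf3 probe set fell by 0.87 there (adjusted p = 0.00791), and the third was at -0.27 and did not pass (0.256).

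The other lists did not stand apart between the fractions (camera, adjusted p 0.136 to 0.751), though fry called the granulocyte and monocyte progenitor list (0.0146) and the immediate early and stress list (0.0219) lower. Granulocyte and monocyte progenitor genes fell in 6 and rose in 2 of 15 cases, with Elane at -2.65, Ms4a3 at -2.59 and Irf8 at 1.93. Cell cycle genes rose in 8 and fell in 5 of 27, among them Bub1b (0.90) and Ccne2 (-1.43), and this list stood higher with quantile normalization (adjusted p = 0.00105) and without the dimmest 40% of genes (0.00121). Among 10 cell cycle inhibitor genes 3 fell and 1 rose, with Cdkn1c at -1.27, and among 15 T lineage genes 3 rose and 3 fell, with Bcl11b at -1.23. Interferon response genes rose in 2 and fell in 2 of 13 cases, with Ifit1 at -1.32 and Ifi27l2a at 1.25. Immediate early and stress genes rose in 4 and fell in 7 of 19, with Ier2 at -1.44 and Dusp1 at -1.29. Stroma genes rose in 3 and fell in 1 of 12, with Col1a2 at -1.78 and Sparc at 1.20, and Rps14 alone of 14 ribosomal protein genes fell, a call lost without any 1 of the WT LMPP or LSK FLT3- arrays (adjusted p 0.0508 to 0.17). Adjusted over the list alone, 9 cell cycle, 4 stroma and 2 cell cycle inhibitor genes rose, 5 cell cycle inhibitor and 0 ribosomal protein genes fell, and the other counts were the same. Of the gate markers Flt3 was 1.99 higher and Kit 1.24 lower, and of the sex-linked genes Uty (-1.04) and Eif2s3y (-0.65) fell, calls that the mean of all probe sets ended (adjusted p = 0.744 and 0.18). That of Eif2s3y was also lost without LSK FLT3- replicate 1 (0.061) and with quantile normalization (0.216).

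The balance of directions depended on the scaling: quantile normalization of the 6 arrays gave 3496 genes, 1656 higher and 1840 lower (47.4% higher), and centring each array on its median gave 6537, 1161 higher and 5376 lower (17.8% higher), with a shift of the median of all genes of -0.12. Without LSK FLT3- replicate 1 or 2 the count was 2370 and 2449.

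A further comparison set E2A-KO LMPP beside WT LSK FLT3-, where genotype and cell fraction differ together. The lymphoid priming genes went both ways: 6 rose and 6 fell of 19, or 7 and 7 adjusted over the list alone. Dntt was 0.86 higher than in WT LSK FLT3- (SE 0.12, adjusted p = 0.00118), while Il7r was 0.74 lower (SE 0.17, adjusted p = 0.01), both genes chosen after their values were seen. Jchain (-4.63) fell furthest, and Foxo1 was 1.18 lower. The list did not stand apart (camera, adjusted p = 0.969); its median was -0.15 and its mean -0.27, while camera's direction was up and fry called it lower (0.0188).

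In this comparison 6822 genes changed, 2002 higher and 4820 lower in E2A-KO LMPP (29.3% higher), and 1358 changed at least 2-fold, 177 higher and 1181 lower. Chl1 (4.38), Wfdc17 (4.33), Plbd1 (2.88), Cd74 (2.62) and H2-Eb1 (2.55) were the largest measured rises, and Tgm2 (-5.89), Igha (-5.59), the megakaryocyte gene Mmrn1 (-4.88), Jchain and Slc18a2 (-4.61) the largest measured falls. Chl1 was at 2.81 in WT LSK FLT3-, and Mmrn1 (3.55), Jchain (3.31) and Slc18a2 (2.97) in E2A-KO LMPP lay below the array median too, so the exact size and rank of these changes carry no weight. All 20 stem cell genes fell here too, with a median of -1.84 (camera, adjusted p = 6.41e-14; adjusted p = 0.0775 with an estimated correlation, the highest of 15 alternatives, lowest 6.59e-19), and so did 14 of 19 megakaryocyte and erythroid genes (camera, adjusted p = 2.71e-05; adjusted p = 0.12 with an estimated correlation, the highest of 15, lowest 1.09e-07). Interferon response genes fell in 8 of 13 cases (camera, adjusted p = 0.0064; adjusted p = 0.248 with an estimated correlation, the highest of 15, lowest 0.00186), led by Ifit1 (-2.32); without the dimmest 40% of genes the call was lost (adjusted p = 0.119). Mature myeloid genes fell in 7 of 12 cases, with Ngp at -2.62, Ltf at -2.14 and Lcn2 at -2.08 (camera, adjusted p = 0.0064; adjusted p = 0.248 with an estimated correlation, the highest of 15, lowest 0.000494).

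Granulocyte and monocyte progenitor genes fell in 8 and rose in 1 of 15 cases, with Elane at -2.29 and Irf8 at 1.72 (camera, adjusted p = 0.0158; adjusted p = 0.283 with an estimated correlation; range 0.00513 to 0.292). Quantile normalization (0.0842) and leaving out the dimmest 40% of genes (0.292) ended this call. NK and dendritic cell genes rose in 6 of 15 cases (camera, adjusted p = 0.000724; adjusted p = 0.213 with an estimated correlation, the highest of 15, lowest 3.23e-07). Notch pathway genes rose in 5 and fell in 1 of 14 (camera, adjusted p = 0.0229; adjusted p = 0.248 with an estimated correlation; range 0.000837 to 0.248), a call lost without E2A-KO LMPP replicate 1 (0.0511), without LSK FLT3- replicate 2 (0.0538) and with the mean of all probe sets (0.202). Among lists that did not stand apart, B lineage and T lineage genes each rose in 4 and fell in 3 cases, of 16 and 15. Cell cycle genes rose in 7 and fell in 3 of 27, cell cycle inhibitor genes rose in 1 and fell in 5 of 10, and immediate early and stress genes rose in 2 and fell in 9 of 19 (camera, adjusted p = 0.0676). The last list passed without E2A-KO LMPP replicate 2 (0.0281) or LSK FLT3- replicate 1 (0.0455), with the replicate number as a block (0.0454), with quantile normalization (0.0124) and with fry (0.00444). The T lineage list passed without the dimmest 40% of genes (0.0153), the cell cycle list so too (0.00478) and with quantile normalization (0.000933), and the cell cycle inhibitor (0.0188) and E protein and Id (0.0166) lists with fry. In the E protein and Id network 2 rose and 4 fell of 9, in the stroma list 3 rose and 1 fell of 12, and 1 of 14 ribosomal protein genes fell. Adjusted over the list alone, 9 interferon response and 10 immediate early and stress genes fell, 1 megakaryocyte and erythroid gene rose, 0 ribosomal protein genes fell, and the other counts were the same.

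Here quantile normalization gave 3617 genes, 1593 higher and 2024 lower (44.0% higher), and median centring 7201, 1053 higher and 6148 lower (14.6% higher), with a shift of the median of all genes of -0.16. Without LSK FLT3- replicate 1 or 2 the count was 2944 and 2989.

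The stage and knockout comparisons were then set against each other, since genes such as Il7r, Ccr9, Cnn3 and Blnk were higher in WT LMPP than in both other groups. Of the 181 genes that fell in E2A-KO LMPP, 90 (49.7%) were among those that rose from LSK FLT3- to LMPP, where independent lists would share 18.8. Of these 90, 58 did not differ past the threshold between E2A-KO LMPP and WT LSK FLT3-, 19 were lower in E2A-KO LMPP and 13 were higher. Of the 69 genes that rose in the knockout, 38 fell from LSK FLT3- to LMPP (16.3 from independent lists), among them Lypd6b, Ffar2, Clec4d and Clec4e. In the same direction, 7 genes rose in both (7.16 from independent lists), and 40 fell in both (42.9), Gimap8 among them. The genes that fell in both depended on the scaling, with 22 under quantile normalization and 56 under median centring, whereas those higher in WT LMPP than in both other groups were 87 and 86 and those lower were 31 and 41. With 1 array left out the 90, 38 and 40 became 33 to 65, 10 to 26 and 9 to 23.

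Both comparisons use the WT LMPP arrays, with opposite sign, so chance pushes their changes apart. In 100 simulations with no effect at most 1 gene was called in both, against 175 observed. As hardly any gene can be called without an effect, this count does not show how many of the 175 come from the shared arrays. The covariance of the log2 changes across genes was -0.03 (-0.0307), against -0.0131 in the simulations, a difference of -0.0176. The simulations gave each gene the same spread in all groups. The SD of the log2 difference between replicates was 0.308 in WT LMPP and 0.195 in WT LSK FLT3-. The -0.0131 may therefore understate what the shared WT LMPP arrays add. Pearson's r was -0.194 across genes, which are not independent replicates, against -0.501 in the simulations. Giving 1 WT LMPP array to each comparison, a split chosen after the data were seen, left 50 and 51 genes that rose at the stage and fell in the knockout (10.8 and 9.6 from independent lists) and 20 and 20 the other way (8.61 and 7.92). In the same direction 10 and 5 rose in both (4.04 and 3.52), and 23 and 29 fell in both (23.1 and 21.6). With the same single WT LMPP array in both comparisons 65 and 58 genes rose and then fell. The covariance was -0.00256 and -0.016 with the split, against -0.0581 and -0.046 with the same array. Both split values were smaller in size than the difference of -0.0176, which is uncertain and may be too large. Part of the 175 may come from the shared arrays, and the split fits still share the arrays that set the spread. Leaving out 1 array gave 53 and 53 (LSK FLT3-), 70 and 84 (E2A-KO LMPP) and 98 and 117 (WT LMPP) genes called in both.

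**Figure D3:**
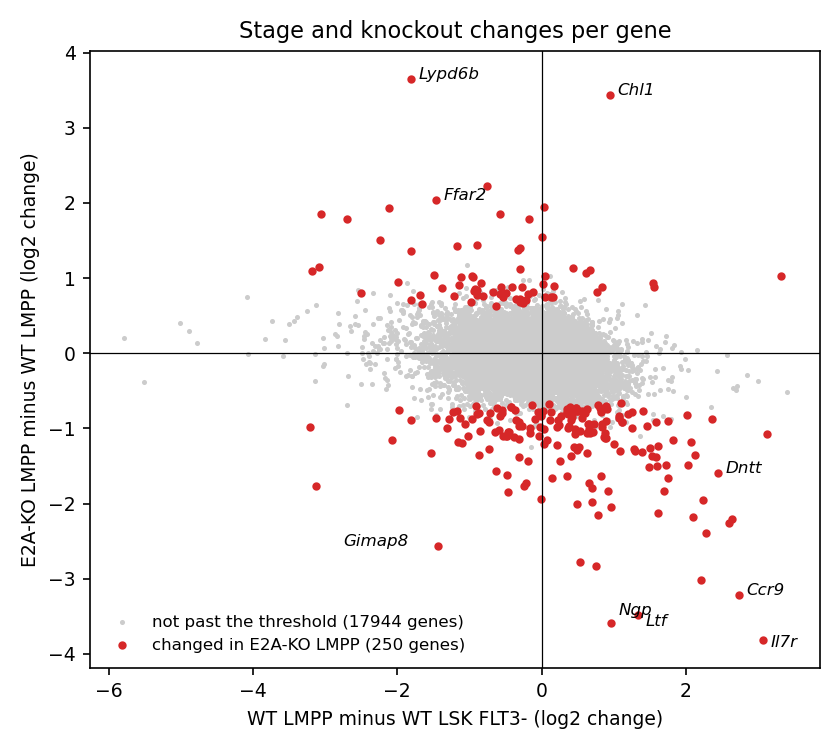
Log2 change of each of 18194 genes from WT LSK FLT3- to WT LMPP (horizontal axis) and from WT LMPP to E2A-KO LMPP (vertical axis), with the 250 genes that changed in the knockout in red (n = 2 arrays per group). Il7r and Ccr9 lie at the lower right, higher in WT LMPP than in both other groups, while Lypd6b and Ffar2 lie at the upper left.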

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

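Probe sets with no gene symbol, or with several, stand outside the gene-level comparisons. Of 10092 such probe sets, 92 were higher and 25 lower in E2A-KO LMPP than in WT LMPP (limma on all probe sets, adjusted p under 0.05), while in the same fit 100 probe sets with 1 gene symbol were higher and 228 lower. Between the wild-type fractions, 1048 of the probe sets with no or several symbols were higher and 553 lower in WT LMPP than in WT LSK FLT3-. Of those with 1 symbol, 2577 were higher and 6447 lower there. The difference in direction is therefore not particular to the knockout. It was not tested. In E2A-KO LMPP against WT LMPP, the largest rise, in a probe set annotated to several genes, was from 3.68 ± 0.02 to 6.06 ± 0.18 (log2, SD, n = 2, change 2.39, SE 0.14, limma adjusted p = 0.000162). The largest fall, also annotated to several genes, was from 6.60 ± 0.02 to 4.58 ± 0.94 (change -2.02, SE 0.34, adjusted p = 0.0303).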

How the results depend on the processing

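The knockout count of 250 genes was 89 on the 4 LMPP arrays alone, 548 with a variance trend and robust estimation, 445 with all probe sets as the unit, 123 with a 2-fold minimum, 508 at an adjusted p under 0.1, and 89 to 164 with 1 array left out. Of the 548 genes 247 were among the 250. The stage count of 6198 was 3496 with quantile normalization (2868 of them shared), 10648 with all probe sets, 1214 with a 2-fold minimum, and 2370 to 6410 with 1 array left out. The count of 6822 for E2A-KO LMPP against WT LSK FLT3- was 3617 with quantile normalization (2978 shared), 12853 with all probe sets, 1358 with a 2-fold minimum, and 2944 to 7515 with 1 array left out. The 175 genes called in both the stage and the knockout comparison became 70 on the 4 arrays of each comparison, 350 with the variance trend, 268 with all probe sets, 51 with a 2-fold minimum, 347 at an adjusted p under 0.1, 53 to 117 with 1 array left out, and 103 and 105 with the WT LMPP arrays split between the comparisons, which was chosen after the data were seen. The changes with stricter or looser thresholds follow from those settings; for the others, fewer arrays included, the cause was not tested. The knockout and stage comparisons and E2A-KO LMPP against WT LSK FLT3- had 5, 7 and 7 called lists. Camera with an estimated correlation kept 0, 0 and 0 of them. The megakaryocyte and erythroid list had an estimated correlation of -0.0181, below the preset 0.01. Its camera adjusted p still went from 2.06e-06 to 0.0939 in the stage comparison. The immediate early and stress list (-0.00774) went from 0.0458 to 0.305 in the knockout. These values argue against a higher correlation as the cause for these lists. The other lists that lost their call had estimates above the preset value. As every called list lost its call, these 2 included, such a loss does not show that the members of a list vary together. The cause was not tested. Fry, which does not compare a list with other genes, called 3 in the knockout and 11 in E2A-KO LMPP against WT LSK FLT3-. With 1 array left out the counts were 3 to 5, 6 to 7 and 6 to 8. In E2A-KO LMPP against WT LSK FLT3-, the lymphoid priming list had camera's direction up and fry's down (median -0.15, adjusted p = 0.0188; range 0.0188 to 0.993 over 15 alternatives), and Nrarp turned from 0.62 to -0.34 with the mean of all probe sets (adjusted p = 0.0529); its probe sets disagree. With the replicate number as a block the counts were 200, 5914 and 6535 genes, 143 in both and 5, 7 and 8 lists. Deviations of same-numbered arrays correlated at 0.0226, -0.022 and -0.0417, so the numbers were not taken as pairs.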

Other observations

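In this part, the tests on single arrays, on quantile normalization and on kappa light chain probe sets were chosen only after the result was seen, as were all gene families.

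Gimap genes, GTPases of the immune-associated family that lie in 1 cluster, were lower in the knockout. Of 8 measured, 6 fell in E2A-KO LMPP against WT LMPP and 0 rose, with a median change of -1.19. Gimap8 (-2.56, SE 0.21), Gimap7 (-2.15, SE 0.14), Gimap6 (-1.56, SE 0.16) and Gimap5 (-1.20, SE 0.17) fell furthest, while Gimap4 was at -0.06 and Gimap3 at -0.33. From WT LSK FLT3- to WT LMPP the family went both ways, with 4 falls and 1 rise, so Gimap8 was lowest in E2A-KO LMPP and highest in WT LSK FLT3-. Under quantile normalization and median centring 6 fell in the knockout too, with medians of -1.23 and -1.22.

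MHC class II genes rose from WT LSK FLT3- to WT LMPP in 6 of 8 cases (5 with median centring), and 0 of 8 changed between the LMPP genotypes. H2-Eb1, H2-Ab1 and H2-Aa were 2.85, 2.70 and 2.69 higher, whereas H2-DMa was at 0.05. In a list of 10 mast cell and basophil genes, 6 fell from WT LSK FLT3- to WT LMPP and 1 rose, and 0 changed with the genotype. The median stage change was -1.44 (-1.33 with quantile normalization, -1.55 with median centring). The falls were Slc18a2 (-5.01), Cpa3 (-3.74), Gata2 (-2.83), Mcpt8 (-2.12), Ms4a2 (-1.64) and Kit (-1.24). Kit is a gate marker and Gata2 is also in the stem cell list. Hdc rose (0.49), and Fcer1a (-0.12), Cma1 (-0.08) and Tpsb2 (0.04) did not pass, so the list did not move as 1. Of 33 Hox genes, 0 changed with the genotype (limma) under the deposited, quantile-normalized or median-centred values. Hoxa9 was the brightest, at 11.47 (log2) in WT LMPP, but most Hox genes lay below the array median of about 4, where fold changes are understated. As 250 of 18194 genes changed with the genotype, hardly any in families of 8, 10 or 33 would by chance. The counts of 0 therefore say little about these families.

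The neutrophil genes Ngp, Ltf and Lcn2 fell by 3.59, 3.48 and 2.83 in E2A-KO LMPP and were also lower there than in WT LSK FLT3-. A single aberrant array is argued against, since the highest adjusted p of the 3 genes without any 1 LMPP array was 0.00229. Mature neutrophils carried into the wild-type sorts, which a lineage-negative gate should remove, may contribute: the other 9 mature myeloid markers had a median change of -0.478 (bootstrap 95% interval -1.72 to 0.01), and of the 5 above log2 6 in an LMPP group 4 fell. The remaining 4 sat near the floor, and S100a8 fell from 9.57 to 7.84 while Lyz2 changed by -0.48, so a carried-over share and a lower granule gene programme within E2A-KO LMPP cannot be told apart here. A direct effect of the genotype was not tested.

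Igha and Jchain were 5.79 and 4.77 higher in WT LSK FLT3- than in WT LMPP. The broader value distribution of the LSK FLT3- arrays is argued against by its small size. Their upper quartile was 6.13 and 6.15 (log2), against 5.78 to 5.82 on the LMPP arrays. Quantile normalization kept at least 95.5% of both changes, but shifts this small could hardly have removed them, so that test adds little. Heavy chain transcription without light chain is argued against as well: 3 probe sets annotated to several kappa light chain genes at once fell too, by 5.01 (-5.01, SE 0.19), 6.00 and 6.18, although the bound for this test was set when the values were known. For plasma cells carried into the LSK FLT3- sort, which a KIT-positive, lineage-negative gate should remove, a bound set beforehand was met: 8 plasma cell genes with low WT LMPP levels had a median change of 0.185 (bootstrap 95% interval -0.16 to 0.55), with 0 lower in WT LMPP and 2 higher (Irf4 0.55, Slamf7 1.20). That bound was set aside after the kappa values were seen. The kappa gene of the fixed list of 16 had dropped out for want of a single-symbol probe set. These 8 genes are dim, but a low WT LMPP level was the rule that chose them, which makes this a weak reason. They were low in WT LSK FLT3- too, from 3.11 (Slamf7) to 4.70 (Mzb1), where Igha was at 10.05. Of the brighter genes Xbp1 (-0.80) and Edem1 (-0.96) were lower in WT LMPP, and Sdc1 (1.54) and Ighm (0.66) were higher. Txndc5 (-0.19) and Creld2 (-0.08) did not pass. The 8 genes gave no sign of plasma cells, but a share too small to lift such dim genes is left open. The kappa falls go with plasma cells. Plasma cells and transcription within the LSK FLT3- cells therefore cannot be told apart here.

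The knockout is on a C57BL/6 background, and genome carried along with the targeted Tcf3 allele could shift its neighbours. Of the 250 genes changed between E2A-KO and WT LMPP, 7 (2.8%) were among the 400 measured genes nearest to Tcf3, where 5.50 would fall by chance (p = 0.312, exact hypergeometric test), and the one-sided upper 95% bound was 5.20%. Among the 50 nearest, 0 changed by limma, where hardly any would by chance. The 400 held no excess of calls that this test could tell from chance, which leaves single neighbours open. As they are few among the 18194 genes tested, they could hardly have held most calls. Their low share therefore decides little. Effects of flanking genome on genes elsewhere were not examined. The direct and indirect effects of losing E2A were not told apart by any test here.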
